A study of Mus musculus with 24 samples.

How the data were processed

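Gene expression was measured by RNA-seq in cells sorted from the cerebral cortex of mouse embryos at day 15.5 (E15.5). The series holds 24 libraries in 6 groups of 4, formed by 3 sorted populations and 2 genotypes. The populations were PAX6+ cells, labelled as radial glia, TBR2+ cells, labelled as intermediate progenitors, and PAX6-TBR2- cells, described as neurons. TBR2 is the protein encoded by Eomes. Libraries called WT here carry the genotype Prdm16 flox/flox in the labels, and KO libraries the same alleles with an Emx1-Ires-Cre allele, a recombinase known to act in the dorsal telencephalic lineage. Groups and replicate numbers were taken from the sample titles. The series text calls the replicates biological, but nothing says which embryos or litters they came from, so the p-values measure only the spread between these libraries.

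Per the labels' protocols, RNA was extracted from the sorted cells with a RecoverAll kit, amplified as cDNA by single primer isothermal amplification with the Ovation RNA-seq V2 system, sheared, and made into libraries with the Ovation Ultralow V2 system. The submitters' processing notes name FastQC, cutadapt, STAR, featureCounts and DESeq2 and the mouse build mm10, without versions. The annotation release and the strand setting are not given in the sources used here. The amplification used no molecular identifiers, so counting error is a lower limit on the technical error, and total RNA amplified this way can carry unspliced transcripts. The deposited count tables hold raw whole-number counts per Ensembl gene, with 2 lane columns per library, which were summed here. The deposited normalized tables hold signal values; DESeq2, which divides the counts of a library by a size factor, is named in the submitters' processing notes, and the values have that form. Within a tolerance of 0.000001, 100% of the values in each column were whole multiples of what 1 read is worth there, so reads could be recovered. For the PAX6+ libraries the recovered reads equalled the raw counts in all 8 columns. In the other populations the recovered reads of a group were 1.44 to 1.7 times its raw counts, and 1 column equalled a raw library. The names of those columns give a group but not a replicate. The raw counts were therefore used for the main results and the recovered reads as an alternative.

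The tables list 39017 genes. Of these, 37693 were named and placed with GENCODE M21 (GRCm38, the assembly of mm10), and 1324 identifiers without a match kept their identifier; they held 0.199% to 0.353% of the counts of a library. Coordinates are 1-based positions in GRCm38. Because the strand setting is unknown, reads of genes that overlap on opposite strands may be mixed. Overlap was taken over whole gene spans and exons were not compared, so how many reads this concerns is not known. An overlapping tested gene was present for 6 of the 51 genes named in PAX6+, 11 of the 38 in TBR2+ and 4 of the 20 in PAX6-TBR2-.

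Library totals were 7.62 to 12.6 M counts in PAX6+, 6.4 to 8.22 M in TBR2+ and 4.95 to 8.64 M in PAX6-TBR2-, apart from 30 M in WT PAX6-TBR2- replicate 4. Before averaging, libraries were compared by a chi-square statistic per degree of freedom over genes with at least 20 reads. The statistic was 5.65 to 45.5 for the 36 pairs of libraries of 1 group and 0.976 to 1.02 for the 24 pairs of lanes of 1 library. Lanes of a library differed by no more than sampling noise and all pairs of libraries by more, so none was taken for 1 library deposited more than once. This does not show that the libraries come from separate embryos.

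KO and WT were compared within each population with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling and the quasi-likelihood F test (glmQLFit, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and adjusted p-values for genes come from this test unless another tool is named. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Differences of the genotype effect between populations were tested as interactions in a fit of both populations, and WT populations were compared in the same way. CPM values are TMM-scaled counts relative to the library total. Those given as WT and KO means of a gene in 1 population are scaled within that comparison, and those of Prdm16 given first for each population, like those in the plot of levels per library, are scaled over all 24 libraries. Library names carry 1 prefix per population, so sequencing and handling cannot be told apart from population, and this limits every comparison between populations.

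The 30 gene lists were radial glia, intermediate progenitor, pan-neuronal, upper-layer neuron, deep-layer neuron, cortical patterning, neuronal migration, axon guidance, cell cycle, Notch signalling, Wnt signalling, BMP and TGF-beta signalling, FGF signalling, oxidative stress defence, nuclear genes of oxidative phosphorylation, the brown fat programme of PRDM16, PRDM family and histone methylation partners, p53 response, immediate early and stress, mitochondrially encoded, ribosomal proteins, interneuron, endothelial and mural, microglia, erythroid, meninges, Cajal-Retzius, choroid plexus and cortical hem, glial precursor, and sex-linked. Lists with at least 5 tested genes were tested against all other genes with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera was repeated with a correlation estimated for each list, and fry was run as a self-contained test of whether a list's genes move, on balance, in 1 direction.

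The genes named in the text followed a rule set before the data were examined, as were the groups, tests, gene lists and most of the alternative settings. For each KO and WT comparison these were Prdm16, Mecom, Pdzrn3, Pax6, Eomes and Emx1 where tested; up to 10 higher and 10 lower called genes of largest fold change with a mean of at least 2 CPM and no overlap between the KO and WT libraries; and up to 3 called members of each list. Symbols of predicted or unnamed genes and sex-linked genes were left out. Where the last 2 parts gave under 15 genes, those of smallest unadjusted p filled the number up to 15, as values that did not pass. Outside the rule, and after their values were seen, Rpl32, Rps14, Rpl8, Gad2, Gad1, Dlx1, Lhx2, Mfge8, Sema3c and Bax were named in PAX6-TBR2- as list members. Also named outside the rule, in the closing observations, were Gabra2 in TBR2+, Gabrb1, Xist, Ddx3y, Eif2s3y, Kdm5d, Uty and the genes that overlap named ones. Interactions took up to 10 genes of largest difference at a mean of at least 2 CPM. Comparisons of WT populations took Pax6 and Eomes, up to 3 members of each cell identity list, and 5 genes on each side of largest fold at a mean of at least 5 CPM.

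WT and KO libraries share replicate numbers, and a fit with the number as a block was planned as an alternative. The numbers were taken to pair the libraries where the deviations from the group means of every same-numbered pair correlated above 0.1. The labels do not say what a number marks. In PAX6+ all 4 pairs passed (0.159 to 0.361), and 8 of 8 libraries correlated best with their own number, so the blocked value is given beside results within PAX6+ where it changes a call or moves a count by more than 1.5 times. The rule was not met in TBR2+ or PAX6-TBR2-, where blocked results are a hint from the data only.

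Each test was run on simulated data drawn from the real means, dispersions and library sizes, with 200 of the better expressed genes changed by 1.5-, 2- or 4-fold. Counts were drawn independently for each gene and library. A structure of the libraries that many genes share is thus left out, and these shares need not hold for the real data. In PAX6+ (13997 genes), 89.6% of genes changed 2-fold and 38.8% of genes changed 1.5-fold were called, and 6.75% of calls were false. In TBR2+ (12476 genes) these shares were 83.6%, 47.8% and 3.75%, and in PAX6-TBR2- (12753 genes) 88.1%, 47.8% and 7.65%. The interaction tests called 62.7% of genes whose effects differed 2-fold in both comparisons with PAX6+ (14149 and 14871 genes) and 67.2% between PAX6-TBR2- and TBR2+ (13429 genes). In the comparisons of WT populations, 88.1% (PAX6+ and TBR2+, 13301 genes), 89.6% (PAX6+ and PAX6-TBR2-, 14120 genes) and 91% (TBR2+ and PAX6-TBR2-, 12723 genes) of genes changed 2-fold were called.

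Alternatives were DESeq2 size factors within edgeR, no filter on low counts, a stricter filter (2 CPM in 4 libraries), DESeq2 1.42.0, the replicate block, limma on log2(value + 1) of the deposited normalized counts, all populations in 1 fit, a minimum log2 fold change of 1, exclusion of mitochondrially encoded, ribosomal RNA and haemoglobin genes, removal of a trend with gene length and GC content, and each library left out in turn. Recovered reads, and WT PAX6-TBR2- replicate 4 thinned to the median total of the other 7 libraries, were added after the data had been seen.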

Results

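Radial glia, intermediate progenitors and neurons of the E15.5 mouse cortex were profiled with and without a conditional knockout of Prdm16, which encodes a zinc finger transcription regulator with a PR domain. Each of the 6 combinations of population and genotype had 4 libraries. Totals ran from 7.75 to 12.6 M counts in WT PAX6+ and from 7.62 to 11.3 M in KO PAX6+. They were 6.42 to 7.6 and 6.4 to 8.22 M in WT and KO TBR2+, and 4.95 to 30 and 6.39 to 8.23 M in WT and KO PAX6-TBR2-. A library held counts for 18406 to 22975 genes. Mitochondrially encoded genes took 11.3% to 24% of the counts in PAX6+, 24.7% to 39.3% in TBR2+ and 20.4% to 26.1% in PAX6-TBR2-.

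The targeted gene was examined first. Prdm16 (ENSMUSG00000039410; GRCm38 chromosome 4, 154316125 to 154636873, minus strand) was most abundant in PAX6+ cells, at 256 ± 34.7 CPM in WT and 188 ± 27.8 CPM in KO (SD, n = 4 each). The ranges, 213 to 295 and 160 to 227, overlapped. The log2 fold change, KO over WT, was -0.43 (SE 0.12) and did not pass (adjusted p = 0.05798 in edgeR). It passed with the replicate block (adjusted p = 0.0004945), and the adjusted p over all other settings ran from 0.0002897 to 0.3696, with 0.02027 in DESeq2. It also passed without WT PAX6+ replicate 4 (-0.51) or without KO PAX6+ replicate 1 (-0.52). In TBR2+ cells Prdm16 was at 55.8 ± 16 CPM in WT and 52.1 ± 7.93 CPM in KO (log2 fold change -0.09, SE 0.17, adjusted p = 0.8998). In PAX6-TBR2- cells it was at 25.2 ± 8.78 and 18.7 ± 7.61 CPM (-0.44, SE 0.27, adjusted p = 0.8136). The labels do not say which exons are floxed, so counts over the whole gene need not vanish after recombination, and they check the genotype labels only in part. Reads of transcripts annotated inside Prdm16 on the opposite strand may be mixed with its own.

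**Figure D1:**
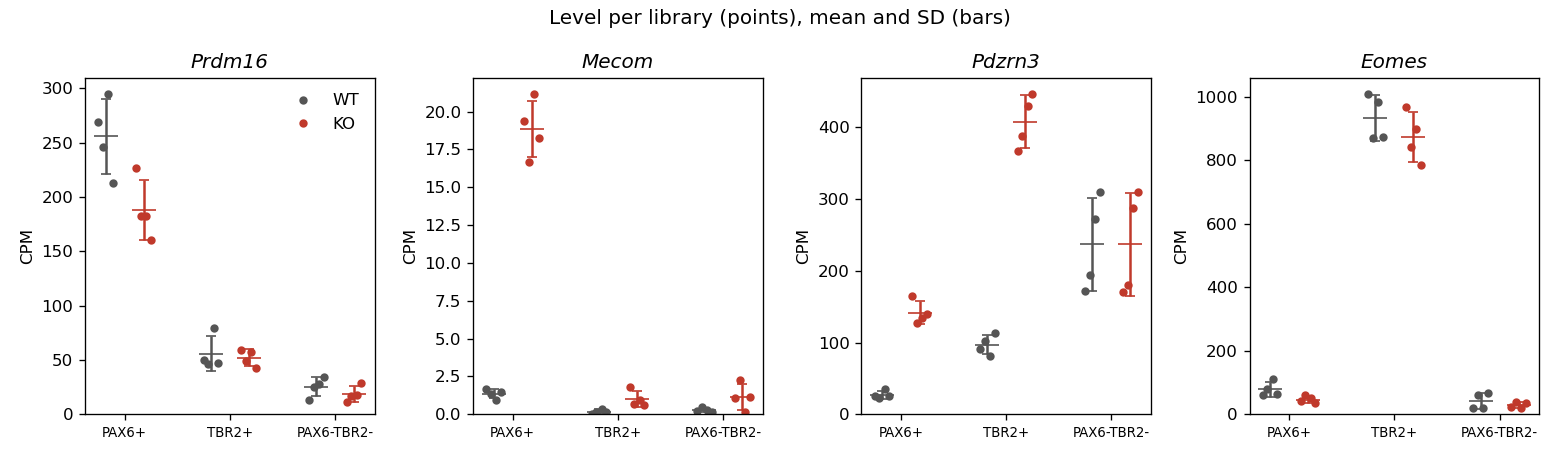
Levels of Prdm16, Mecom, Pdzrn3 and Eomes in each of the 24 libraries, as CPM scaled over all libraries, by sorted population on the x axis (grey WT, red KO; bars give the mean and SD of 4 libraries). Pdzrn3 averaged 27.3 CPM in WT and 141 CPM in KO PAX6+ cells, 97.3 and 408 CPM in TBR2+ cells, and 237 CPM in both genotypes of PAX6-TBR2- cells.

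KO and WT PAX6+ cells were compared to ask which genes change with the knockout in radial glia. By the labels' genotypes, the Cre allele is present in KO libraries only. An effect of Cre or of the altered Emx1 allele thus cannot be told apart from loss of Prdm16 in any population. Mecom, which encodes a close relative of PRDM16, rose 14.3-fold, from 1.67 ± 0.383 to 23.6 ± 2.31 CPM (SD, n = 4 each; log2 fold change 3.84, SE 0.21, adjusted p = 3.035e-08). In TBR2+ and PAX6-TBR2- cells its counts were too low to test. Scaled over all libraries, its means in WT and KO were 0.174 and 1 CPM in TBR2+, and 0.277 and 1.15 CPM in PAX6-TBR2-. A rise outside PAX6+ cells is thus not ruled out. Pdzrn3, which encodes a RING-type ubiquitin ligase, rose 5.24-fold, from 33.7 ± 6.28 to 177 ± 18.5 CPM (2.39, SE 0.14, adjusted p = 3.035e-08). Genes of 2 GABA-A receptor subunits rose, Gabra2 from 5.03 ± 2.84 to 95.4 ± 10.1 CPM and Gabrg1 from 1.24 ± 0.666 to 18.9 ± 7.29 CPM. The retinoic acid hydroxylase gene Cyp26b1 rose from 0.435 ± 0.284 to 19 ± 3.61 CPM, the largest fold change among genes passing the naming rule (log2 fold change 5.40, SE 0.33). Shisa9, which encodes an AMPA receptor auxiliary subunit, rose by 3.16 on the log2 scale, and Robo3, which encodes an axon guidance receptor, by 2.96. Slc35d3 (4.62), Moxd1 (3.01), Cckar (3.00) and Fgf15 (2.87) rose from under 1 CPM. Among genes that fell, Col12a1 dropped from 156 ± 48.4 to 24.2 ± 3.64 CPM (log2 fold change -2.69, SE 0.19) and Col22a1 from 7.39 ± 4.01 to 0.351 ± 0.207 CPM (-4.34), both encoding collagens. Smoc1 (-2.80), Palmd (-2.28), Slc14a2 (-2.52), Sall4 (-2.43), Ankfn1 (-2.86), Minar1 (-2.56), Tmem108 (-2.24) and the semaphorin gene Sema3c (-2.65) fell too. Cyp26b1 and Pdzrn3 lie on chromosome 6, as does Emx1, which carries the Cre allele. In all genes given here as risen or fallen the 4 KO libraries lay on 1 side of the 4 WT libraries. The naming rule required this of genes chosen by fold change, so it is no further evidence. Of 14212 genes tested, 517 passed in edgeR, 348 higher and 169 lower in KO. With the replicate block 1045 passed (609 higher, 436 lower), including all 517.

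Among the cell identity lists, 3 of 20 radial glia genes passed in PAX6+ cells: Ednrb (0.54) and Slc1a3 (0.43) rose and Mfge8 (-0.97) fell. Adjusted over the list alone, 4 rose and 1 fell. Of 15 intermediate progenitor genes, Eomes (-0.74, SE 0.19, adjusted p = 0.0358) and Insm1 (-0.52) fell and 13 did not pass. Adjusted over the list alone, 1 rose and 3 fell. Of 17 pan-neuronal genes, Syt1 (1.36) and Stmn4 (0.96) rose and Dcx (-1.01) was 1 of 2 that fell. Adjusted over the list alone the counts were 2 and 5. Of 13 upper-layer neuron genes, Mdga1 (0.85) and Dok5 (0.50) rose and Unc5d (-1.26) fell (5 and 3 adjusted over the list alone). Of 12 deep-layer neuron genes 1 passed, Foxp2 (-0.94), which fell (1 higher and 2 lower adjusted over the list alone). The patterning regulators Dmrt3 (0.49) rose and Gli3 (-0.37) fell, with 10 of 12 not passing (1 higher and 1 lower adjusted over the list alone). Pax6 was at -0.03 (adjusted p = 0.944) and Emx1 at -0.36 (adjusted p = 0.409). None of these 6 lists was called by camera, with adjusted p-values of 0.122 (radial glia), 0.2739 (intermediate progenitor), 0.1353 (pan-neuronal), 0.4019 (upper-layer), 0.282 (deep-layer) and 0.9734 (cortical patterning). With the block the radial glia list was called higher (adjusted p = 0.04563), though not with an estimated correlation as well (adjusted p = 0.3206). The median and mean of the upper-layer list had different signs (0.06 and -2e-04). Several of these gene calls were lost on leaving out 1 library: Gli3 in 6 of 8 such fits, Eomes and Slc1a3 in 5, Dmrt3 in 4, Insm1, Unc5d and Dok5 in 3, Stmn4 in 2 and Mdga1 in 1. The highest adjusted p on leaving out 1 library was 0.1651 for Eomes (without WT replicate 3), 0.1476 for Slc1a3 and 0.08893 for Insm1 (both without WT replicate 2). It was 0.05611 for Stmn4 and 0.05262 for Mdga1 (both without KO replicate 3), 0.05639 for Unc5d and 0.1018 for Dmrt3 (both without WT replicate 1), 0.06632 for Dok5 (without WT replicate 3) and 0.1748 for Gli3 (without KO replicate 2). With all populations in 1 fit Eomes, Ednrb, Slc1a3, Dok5, Dmrt3 and Gli3 did not pass, and with a length and GC trend removed Insm1 did not.

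Genes of neuronal migration and axon guidance moved in both directions in PAX6+ cells. Of 23 migration genes, 5 rose, among them Pdzrn3 and Filip1 (1.69), and 3 fell, among them Sema3c (6 and 3 adjusted over the list alone). Its median was -0.05 and its mean 0.10, and it was not called (adjusted p = 0.2739). Of 18 axon guidance genes 4 rose, including Sema6d (2.48, SE 0.19, from 28.6 to 161 CPM), Epha3 (1.68) and Ephb1 (0.63), and Unc5d fell (6 and 2 adjusted over the list alone). Ephb1 did not pass with all populations in 1 fit. Of the list 9 genes lay above and 9 below 0, with a median of 0.03 and a mean of 0.24. It was called higher by camera (adjusted p = 0.03866), though not with an estimated correlation (adjusted p = 0.2303) or without KO PAX6+ replicate 3 (0.08019) or replicate 1 (0.0613).

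Among signalling lists in PAX6+ cells, FGF signalling was called higher: 11 of 13 genes had fold changes above 0, with a median of 0.26, and Fgf15 passed (2 adjusted over the list alone). Its camera adjusted p was 0.001926, and adjusted p = 0.2303 with an estimated correlation. Wnt signalling was called lower (12 of 18 below 0, median -0.12; adjusted p = 0.04759, and adjusted p = 0.3181 with an estimated correlation), with Fzd5 (-1.03) the gene of 18 that passed and 3 adjusted over the list alone. That call was lost with the block (adjusted p = 0.06757) and without WT replicate 1 (0.131), WT replicate 4 (0.12) or KO replicate 4 (0.2122). Fzd5 was lost without any 1 of the 8 libraries (highest adjusted p = 0.1328, without WT replicate 3), without a filter and with all populations in 1 fit. In the BMP and TGF-beta signalling list Id2 (0.69) and Bmpr1b (0.49) rose, 2 also adjusted over the list alone. It was not called (adjusted p = 0.06298) but passed with the block (0.03447), though not with the block and an estimated correlation (adjusted p = 0.3206). The call of Bmpr1b was lost in 7 of the 8 fits that leave out 1 library, all but that without WT replicate 4 (highest adjusted p = 0.17, without WT replicate 2), with DESeq2 size factors and with limma. In the Notch list the ligand gene Jag1 fell (-1.58, SE 0.22) and 13 of 14 genes did not pass (1 higher and 1 lower adjusted over the list alone). Its median was 0.04 and its mean -0.11 (adjusted p = 0.7335).

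Cell cycle genes were lower in KO PAX6+ cells as a list: 21 of 21 had fold changes below 0, with a median of -0.15, though none passed singly, also adjusted over the list alone (camera adjusted p = 0.001926, and adjusted p = 0.2303 with an estimated correlation). Ribosomal protein genes showed the same, 19 of 20 below 0 with a median of -0.20 (adjusted p = 0.001532; adjusted p = 0.2303 with an estimated correlation). Their share of the counts was 0.382% to 0.413% in WT and 0.332% to 0.387% in KO libraries. Nuclear genes of oxidative phosphorylation were lower too, 17 of 20 below 0 (median -0.12; adjusted p = 0.03866, and adjusted p = 0.3181 with an estimated correlation), a call lost without KO replicate 3 (0.1352), WT replicate 3 (0.0789) or WT replicate 4 (0.109). Without WT PAX6+ replicate 2, 14 lists were called in place of 9. Not called were oxidative stress defence (adjusted p = 0.08605; 1 lower, Ppargc1a at -0.47, also adjusted over the list alone), PRDM family and histone methylation partners (0.1629; 1 higher, Mecom, also adjusted over the list alone), p53 response (0.8126), immediate early and stress (0.0886, and 0.04563 with the block, though adjusted p = 0.3206 with the block and an estimated correlation), mitochondrially encoded (0.1794) and sex-linked genes (0.2739; median 8e-04 and mean 0.04, tested as lower). The brown fat list had 4 genes measured and no list test; Ppargc1a fell in it (1 higher and 3 lower adjusted over the list alone), a call lost in 7 of the 8 fits that leave out 1 library, all but that without KO replicate 3 (highest adjusted p = 0.1852, without KO replicate 2), and with all populations in 1 fit.

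Marker lists of 3 other cell types were called lower in KO PAX6+ libraries. Interneuron genes were called lower (7 of 9 below 0, median -0.54; adjusted p = 0.02733), with Gad2 passing (-1.68, from 5 ± 2.47 to 1.52 ± 0.512 CPM). Endothelial and mural genes were called lower (7 of 7 below 0, median -0.72; adjusted p = 0.01168), as were Cajal-Retzius genes (6 of 6 below 0, median -1.31; adjusted p = 0.02733). Adjusted over the list alone, 1 gene fell in each. With an estimated correlation the adjusted p was 0.3181, 0.3251 and 0.4467 for these 3 lists. The interneuron call was lost without WT replicate 1 (0.1526), KO replicate 3 (0.0624) or KO replicate 4 (0.0814), and the endothelial and mural call without KO replicate 4 (0.1635) or KO replicate 2 (0.0564). The Cajal-Retzius call was lost without WT replicate 3 (0.2325), KO replicate 1 (0.107) or KO replicate 4 (0.0814). Slco1c1 (-2.03, groups overlapping), Col1a2 (-2.06) of the meninges list and Aqp4 (-1.66) of the glial precursor list (adjusted p = 0.0566 as a list) passed singly. Their highest adjusted p was 0.2158 without WT replicate 3, and 0.05794 and 0.07622 without WT replicate 1, and that of Gad2 was 0.1057 without WT replicate 1. Slco1c1 and Aqp4 were lost in 4 of 8 such fits, Gad2 in 3 and Col1a2 in 1. Slco1c1 did not pass with DESeq2 or limma. Microglia, erythroid and choroid plexus genes had 2 members measured each, with median log2 fold changes of 0.41, -0.84 and -0.30, and meninges 3 (-0.79), too few for a list test. Adjusted over the list alone, 1 erythroid and 1 meninges gene fell.

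In TBR2+ cells, labelled as intermediate progenitors, Ptx3, which encodes a secreted pentraxin, rose 10.8-fold, from 4.72 ± 2.03 to 50.4 ± 2.93 CPM (SD, n = 4 each; log2 fold change 3.43, SE 0.20, adjusted p = 2.889e-07). Pdzrn3 rose 4.21-fold, from 82.2 ± 10.7 to 346 ± 26.5 CPM (2.07, SE 0.11, adjusted p = 1.048e-07), and the AP-1 family gene Fosl2 5.34-fold, from 12.6 ± 5.05 to 67.1 ± 8.84 CPM. Ppp1r14c (2.85), Veph1 (2.59), Daam2 (2.41), Rcan2 (2.12), Adamts20 (2.30), Gabrg1 (2.11), Rassf10 (3.19) and the opioid receptor gene Oprd1 (2.98) rose as well. Smoc1 fell from 10.2 ± 3.47 to 0.878 ± 0.505 CPM (log2 fold change -3.49, SE 0.38), and the cell adhesion gene Dscaml1 from 98.3 ± 10.6 to 25.3 ± 4.99 CPM (-1.96). The receptor tyrosine kinase gene Alk (-2.56), the homeobox gene Pbx3 (-2.16), C79798 (-2.16), Tgfa (-2.10), Agbl4 (-1.87), Thsd4 (-1.73), Fign (-1.66) and Dusp26 (-1.65) fell. Tgfa also lies on chromosome 6. Ptx3 lies inside the span of Veph1 and C79798 inside that of Pbx3, on opposite strands. Whether their exons overlap was not examined, so their reads may be mixed in part. Eomes (-0.09, adjusted p = 0.8002), Pax6 (-0.07, 0.9309) and Emx1 (-0.23, 0.3805) did not pass. Of 12687 genes, 223 passed in edgeR, 139 higher and 84 lower. The count was 121 without WT replicate 3, 137 without WT replicate 1, 139 without KO replicate 2, 142 without KO replicate 3 and 420 without KO replicate 1. On leaving out 1 library the call of C79798 was lost in 6 of 8 fits and those of Thsd4 and Fign in 5, with a highest adjusted p of 0.1633 and 0.1041 (both without KO replicate 3) and 0.1176 (without WT replicate 1). C79798 did not pass with limma, nor Fign with all populations in 1 fit. With DESeq2 356 genes passed, and without a filter 728. The replicate block gave 720, though the numbers do not meet the pairing rule there. With a length and GC trend removed 123 were higher and 117 lower.

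Deep-layer neuron genes were higher in KO TBR2+ cells: Sox5 (0.80, SE 0.12), Fezf2 (0.71) and Nr4a2 (0.64) rose, 12 of 15 had fold changes above 0, and 6 rose and 1 fell adjusted over the list alone (median 0.64; camera adjusted p = 6.39e-05, and adjusted p = 0.4937 with an estimated correlation). Of 13 upper-layer genes, Rorb (0.64) rose and 4 fell, including Pou3f1 (-1.54, SE 0.20), Cux2 (-0.59) and Unc5d (-0.55). Adjusted over the list alone 5 rose and 5 fell, and the list was not called (adjusted p = 0.2372). Of 18 radial glia genes Ptprz1 rose (1.35; 3 adjusted over the list alone), and the list was called higher (12 of 18 above 0, median 0.23; adjusted p = 0.01552, and adjusted p = 0.6618 with an estimated correlation), a call lost without KO replicate 1 (0.5842), WT replicate 4 (0.307) or WT replicate 2 (0.0556). Of 15 intermediate progenitor genes Kif26b fell (-0.95, SE 0.12; 2 adjusted over the list alone; list adjusted p = 0.1025), and of 17 pan-neuronal genes none passed (2 lower adjusted over the list alone; list adjusted p = 0.1025). Robo2 (-0.68), a receptor of Slit proteins, and Epha7 (-0.60) fell, and Sema6d (0.61) rose, among migration and guidance genes. Those lists had adjusted p-values of 0.4245 and 0.8997, with 2 higher and 2 lower, and 2 higher and 4 lower, adjusted over the list alone. Cajal-Retzius genes were called higher, 9 of 9 above 0 with a median of 0.57, none passing singly (adjusted p = 0.0005664, and adjusted p = 0.4937 with an estimated correlation). On leaving out 1 library the highest adjusted p was 0.06197 for Fezf2, 0.06927 for Cux2 and 0.1042 for Unc5d (all without WT replicate 3). It was 0.1469 for Nr4a2 and 0.1287 for Sema6d (both without KO replicate 2), 0.06773 for Rorb (without WT replicate 2) and 0.08451 for Ptprz1 (without KO replicate 3). Of 8 such fits, Nr4a2 and Sema6d were lost in 6, Ptprz1 and Unc5d in 4, Fezf2 in 3, and Cux2 and Rorb in 2. With all populations in 1 fit Cux2, Rorb, Unc5d and Sema6d did not pass. Nr4a2 and Sema6d were lost with limma and with recovered reads, and Sema6d also with a length and GC trend removed.

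Cell cycle genes were lower as a list in KO TBR2+ cells, 20 of 21 below 0 with a median of -0.47 (camera adjusted p = 3.001e-07, and adjusted p = 0.4937 with an estimated correlation). None passed over all genes, and 2 fell adjusted over the list alone. Ribosomal protein genes (17 of 20 below 0, median -0.23; adjusted p = 5.949e-05, and adjusted p = 0.4078 with an estimated correlation) and nuclear genes of oxidative phosphorylation (19 of 20 below 0, median -0.18; 9.824e-05 and adjusted p = 0.4937 with an estimated correlation) were called lower, with no member passing. Mitochondrially encoded genes were called higher (8 of 8 above 0, median 0.23; adjusted p = 0.00212, and adjusted p = 0.5151 with an estimated correlation), a call lost without WT replicate 2 (0.1325). They took 24.7% to 33.1% of the counts in WT and 30.5% to 39.3% in KO libraries. Genes of BMP and TGF-beta signalling were called higher (9 of 11 above 0; 2 rose adjusted over the list alone; adjusted p = 0.0222, and adjusted p = 0.4078 with an estimated correlation), a call lost without WT replicate 4 (0.05992), WT replicate 2 (0.0556), KO replicate 1 (0.0576) or KO replicate 4 (0.0562). The Notch feedback gene Nrarp fell (-1.15, SE 0.14), also adjusted over the list alone, with the list at an adjusted p of 0.8997. Wnt (0.908; 1 higher adjusted over the list alone), FGF (0.2465), cortical patterning (0.5936), oxidative stress defence (0.2239), PRDM family (0.8997), p53 (0.3366; 1 lower adjusted over the list alone), immediate early (0.8997; median -0.08, mean 0.0044; 1 higher adjusted over the list alone) and sex-linked genes (0.6236; median 0.08 and mean 0.09, tested as lower) were not called. Interneuron, endothelial, choroid plexus and brown fat genes had 3 members measured each (medians 0.06, -0.34, -0.02 and 0.02) and erythroid genes 2 (-0.10), and no microglia, meninges or glial precursor gene was measured well enough to test. The list count fell from 8 to 5 without WT replicate 2.

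In PAX6-TBR2- cells, labelled as cortical neurons, 1 of 12928 genes passed in edgeR. Ppp1r14c, which encodes an inhibitor of protein phosphatase 1, rose 3.00-fold, from 5.03 ± 0.756 to 14.7 ± 1.73 CPM (SD, n = 4 each; log2 fold change 1.58, SE 0.18, adjusted p = 0.006195). Its adjusted p was 0.05744 with all populations in 1 fit, and ran from 3.087e-07 to that value over the alternatives. The same gene rose in TBR2+ cells. Ptx3 (1.83, SE 0.29), Tmem158 (-1.64), Btbd17 (-1.67), Pfdn5 (-0.63), Slc44a5 (0.70) and Plxnc1 (0.59) shared an adjusted p of 0.1062. Cdh4 (-0.54), Fam210b (-0.69), Itga6 (0.59), Rplp0 (-0.59), Unc5d (-0.71), Diras2 (1.15), Stmn3 (-0.49) and Gabra2 (0.69) had adjusted p-values of 0.1125 to 0.1888, and none passed. Pdzrn3 was at 0.01 (SE 0.20, adjusted p = 0.9966), Eomes at -0.55 (0.8133), Pax6 at -0.16 (0.9375) and Emx1 at -0.60 (0.5287). At an unadjusted p under 0.05 there were 854 genes, and DESeq2 called 24 and edgeR without a filter 38. With the replicate block 153 genes passed (57 higher, 96 lower), though the numbers do not meet the pairing rule there. Without WT replicate 4, the library of 30 M counts, 2 genes passed, and without KO replicate 4, 3.

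Ribosomal protein genes were lower in KO PAX6-TBR2- cells, 18 of 19 below 0 with a median of -0.38; none passed over all genes and 10 fell adjusted over the list alone, among them Rpl32 (-0.51), Rps14 (-0.50) and Rpl8 (-0.49). The list was called by camera (adjusted p = 1.351e-09) and fry (0.02338), with adjusted p = 0.08682 with an estimated correlation. Interneuron genes were called higher, 15 of 15 above 0 with a median of 0.34, such as Gad2 (0.56, SE 0.27), Gad1 (0.46, SE 0.25) and Dlx1 (0.41, SE 0.33), none passing (adjusted p = 8.983e-05, and adjusted p = 0.6647 with an estimated correlation). Genes of cortical patterning were called lower (10 of 12 below 0; adjusted p = 0.005877, and adjusted p = 0.6228 with an estimated correlation), with Emx1 and Lhx2 (-0.53) falling adjusted over the list alone. The call was lost without WT replicate 2 (0.1048) or KO replicate 1 (0.0763). Genes of the upper-layer neuron list were called lower (11 of 14 below 0; 1 higher and 2 lower adjusted over the list alone; 0.01679, and adjusted p = 0.6228 with an estimated correlation). The call was lost without WT replicate 3 (0.1596), KO replicate 1 (0.0683) or KO replicate 2 (0.0948). Genes of the intermediate progenitor list were called lower (11 of 14 below 0; 1 lower adjusted over the list alone; 0.04962, and adjusted p = 0.8225 with an estimated correlation). That call was lost without WT replicate 4 (0.6933), WT replicate 2 (0.587), KO replicate 1 (0.392) or KO replicate 3 (0.212). Nuclear genes of oxidative phosphorylation were called lower (15 of 20 below 0; 0.0009703, and adjusted p = 0.319 with an estimated correlation). Without KO replicate 1 the count of lists fell from 6 to 3.

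The other lists were not called in PAX6-TBR2- cells: radial glia (adjusted p = 0.8078; Mfge8, at -1.54, lower adjusted over the list alone), pan-neuronal (0.07578), deep-layer (0.7203), neuronal migration (0.7203; Sema3c, at -0.70, lower adjusted over the list alone), axon guidance (0.7203; Unc5d lower adjusted over the list alone), cell cycle (0.3897; 15 of 19 below 0), Notch (0.7929), Wnt (0.2875), BMP and TGF-beta (0.9159), FGF (0.7203), oxidative stress defence (0.2875), p53 (0.3137; Bax, at -0.65, lower adjusted over the list alone), immediate early (0.7203), endothelial and mural (0.4874), Cajal-Retzius (0.5587) and sex-linked (0.7203). Mitochondrially encoded genes (0.9043) had a median of 0.07 and a mean of -0.16, and PRDM family genes (0.8651) a median of 0.01 and a mean of -0.01. Microglia (4 genes measured, median 0.02), brown fat (3, 0.11), erythroid (2, -0.21), choroid plexus (2, 0.10) and glial precursor genes (1, 0.15) were too few for a list test, and no meninges gene could be tested.

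Whether the effect of the knockout differed between populations was tested as an interaction. Between TBR2+ and PAX6+ cells 89 of 14548 genes differed, 31 with a more positive and 58 with a more negative log2 fold change in TBR2+ (edgeR adjusted p under 0.05). Cyp26b1 (difference -4.72, SE 0.69; log2 fold change 5.40 in PAX6+ and 0.67 in TBR2+) and Shisa9 (-3.57, SE 0.37; 3.16 and -0.40) had more positive fold changes in PAX6+, as did Gabra2 (-2.48), Cckar (-2.79) and Kcna2 (-2.60). Differences were positive for Rassf10 (4.21; log2 fold change -0.998 in PAX6+ and 3.19 in TBR2+), Sema3c (2.90; -2.65 and 0.25) and Ndrg1 (2.81; -1.66 and 1.15). They were so too for Col22a1 (4.18; -4.34 in PAX6+) and Mme (2.75; -1.94 in PAX6+), whose counts in TBR2+ alone were too low to test there. Kcna2 was lost in 5 of the 16 fits that leave out 1 library (highest adjusted p = 0.06709, without WT PAX6+ replicate 3), and 137 genes differed without KO TBR2+ replicate 1. Between PAX6-TBR2- and PAX6+ cells 117 of 15102 genes differed, 30 with a more positive and 87 with a more negative log2 fold change in PAX6-TBR2-. Gabra2 (-3.54, SE 0.31, adjusted p = 2.605e-06), Prokr2 (-3.32), Shisa9 (-3.00), Cyp26b1 (-4.24) and Pdzrn3 (-2.38, SE 0.27) had more negative fold changes in PAX6-TBR2-, as did Npy (-5.88, SE 1.16; 0.12 in PAX6-TBR2-), Plcxd3 (-4.11) and Kcna6 (-3.91). Differences were positive for Ppp1r1b (3.37, with -3.63 in PAX6+ and -0.23 in PAX6-TBR2-) and Grm5 (2.37, with 0.54 in PAX6-TBR2-, not tested in PAX6+ alone). Grm5 was lost in 12 of 16 such fits (highest adjusted p = 0.1884, without WT PAX6+ replicate 3) and with the replicate block. Npy was not tested in PAX6+ alone either, nor Cyp26b1 in PAX6-TBR2- alone. Between PAX6-TBR2- and TBR2+ cells 7 of 13725 genes differed. Differences were negative for Fosl2 (-2.28; 2.42 in TBR2+ and 0.14 in PAX6-TBR2-), Pdzrn3 (-2.06; 2.07 and 0.01), Prokr2 (-2.06; 1.45 and -0.60) and Slc17a6 (-0.89; 0.23 and -0.66). They were positive for Pbx3 (2.19; -2.16 and 0.04), Dscaml1 (1.86; -1.96 and -0.10) and Akap12 (1.26; -1.33 and -0.07). Of these, Akap12 was lost in 13, Slc17a6 in 12, Pbx3 in 5 and Prokr2 in 3 of the 16 fits that leave out 1 library. The highest adjusted p was 0.1104, 0.1528 and 0.07838 for the first 3 (without KO PAX6-TBR2- replicate 3) and 0.0667 for Prokr2 (without KO TBR2+ replicate 2). DESeq2 called 27 genes and edgeR without a filter 126, each including these 7. With the replicate block Fosl2, Pbx3, Prokr2, Akap12 and Slc17a6 did not pass, though the numbers do not meet the pairing rule in either population. The count was 4 without WT TBR2+ replicate 1 and 3 without WT TBR2+ replicate 3, KO TBR2+ replicate 2 or KO PAX6-TBR2- replicate 3. Library handling coincides with population, which limits these comparisons. Of 100 drawn splits of the libraries 5 reached 89 genes, 4 reached 117 and 6 reached 7 in the 3 comparisons, so chance is not excluded for these counts.

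How far the fold changes were shared was measured across genes, which are not independent replicates. The Pearson correlation was 0.322 between TBR2+ and PAX6+ (Spearman 0.303; 12253 genes), 0.241 between PAX6-TBR2- and PAX6+ (0.265; 12236 genes) and 0.366 between PAX6-TBR2- and TBR2+ (0.374; 12077 genes). TBR2+ and PAX6+ shared 46 genes called higher, against 3.18 for independent calls, and 20 called lower, against 0.811, while 2 and 1 were called in opposite directions. Of the genes called in PAX6+ cells, 83.7% of 436 had the same direction in TBR2+ (median 0.30, against 0.79 where called) and 77.3% of 444 in PAX6-TBR2- (median 0.14). Of those called in TBR2+ cells, 83.3% of 204 had the same direction in PAX6+ (median 0.34, against 0.79 where called) and 85.3% of 204 in PAX6-TBR2- (median 0.21). Genes chosen by a call have larger values where they were called through that choice alone, so the smaller medians elsewhere do not show a smaller effect. The populations share no libraries, but same-numbered libraries could be of the same embryos, which the labels do not say. The counts for independent calls then need not be those without a genotype effect. When both populations were regrouped alike, another split reached a correlation of 0.323 between TBR2+ and PAX6+. Another reached 0.284 between PAX6-TBR2- and PAX6+, so chance is not excluded for either correlation. Between PAX6-TBR2- and TBR2+ the highest other was 0.286, but the regrouping ties replicate numbers that need not match there.

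**Figure D2:**
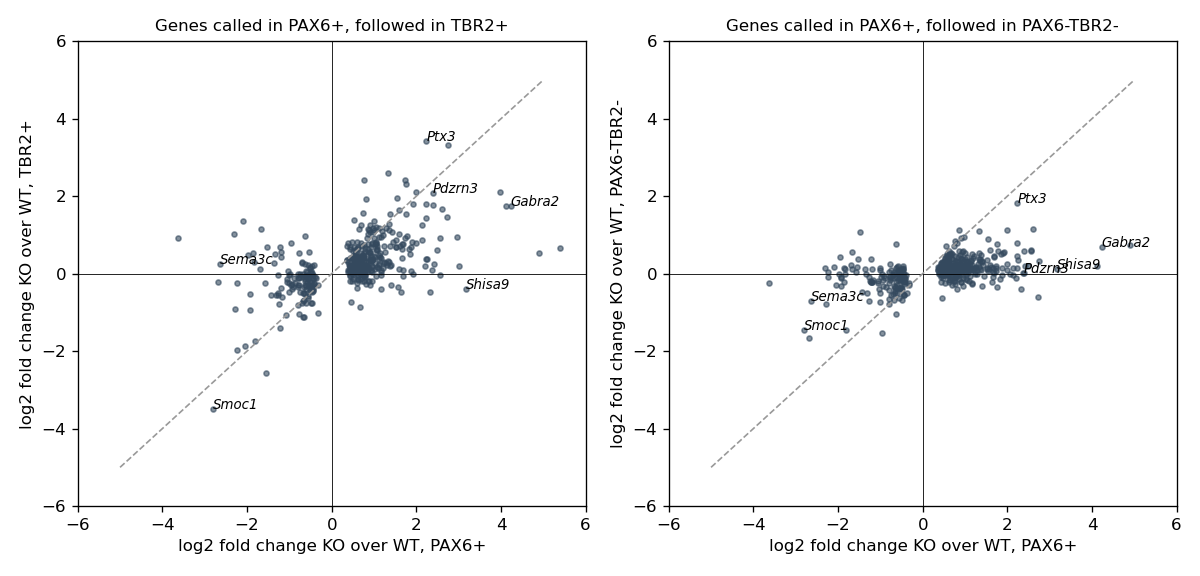
Log2 fold changes, KO over WT, of the genes called in PAX6+ cells (x axis) against those in TBR2+ cells (left) and PAX6-TBR2- cells (right) on the y axis, 1 point per gene, with a dashed line of equality. Most points share their direction (83.7% and 77.3%); the genes were chosen by their call on the x axis, which by itself makes values on that axis larger.

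The sort was examined by comparing WT populations. Pax6 was 1.78-fold higher in PAX6+ than in TBR2+ cells (log2 difference 0.83, SE 0.12) and 14.1-fold higher than in PAX6-TBR2- cells (3.82, SE 0.23), and 7.87-fold higher in TBR2+ than in PAX6-TBR2- cells. Eomes was 12.1-fold higher in TBR2+ than in PAX6+ cells and 21.4-fold higher than in PAX6-TBR2- cells. Between PAX6+ and PAX6-TBR2- the difference was 0.84 (adjusted p = 0.02764), lost without WT PAX6+ replicate 3 (0.08758) and also without WT PAX6-TBR2- replicate 1 or 3, and with DESeq2. Radial glia genes were higher in PAX6+ than in TBR2+ cells in 20 of 20 cases, such as Notch2 (22.2-fold) and Nes (11.2-fold), and in 19 of 20 than in PAX6-TBR2- cells. Of 15 intermediate progenitor genes, 14 were higher in TBR2+ than in PAX6+, such as Sstr2 (45.7-fold) and Kif26b (65.9-fold), and 15 than in PAX6-TBR2-. All 17 pan-neuronal genes measured were higher in TBR2+ than in PAX6+, such as Tubb3 (49.2-fold) and Neurod6 (147-fold), and 18 of 18 were higher in PAX6-TBR2- than in PAX6+. TBR2+ and PAX6-TBR2- were less apart. Of 18 such genes, 12 were higher in PAX6-TBR2- and 2, Elavl4 (3.83-fold) and Rbfox3 (3.01-fold), in TBR2+. Scaled over all libraries, Neurod6 was at 1130 CPM in TBR2+ and 1120 CPM in PAX6-TBR2-, and Tubb3 at 423 and 492 CPM. Cell cycle genes were higher in PAX6+ than in TBR2+ and in TBR2+ than in PAX6-TBR2- in 21 of 21 cases each. In PAX6-TBR2- cells 14 of 15 interneuron genes were higher than in either other population, with Gad1 200-fold and Lhx6 240-fold higher than in TBR2+, and 5 of 5 microglia genes were higher than in PAX6+. In all, 8570 of 13550 genes (63.2%) differed between PAX6+ and TBR2+, 9530 of 14308 (66.6%) between PAX6+ and PAX6-TBR2-, and 6309 of 12868 (49%) between TBR2+ and PAX6-TBR2- (edgeR). Differences in handling coincide with the populations and are included in these counts.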

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

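The tests of read mapping at Pdzrn3 and of standard errors in PAX6-TBR2- were chosen after the results were seen. The sequencing total of WT PAX6-TBR2- replicate 4, 30 M counts, lay apart from the other libraries of its group (4.95 to 8.64 M). The other 12 values that lay apart from their groups were each the CPM of a named gene in 1 library. In KO PAX6+ cells these were replicate 4 for Emx1 (14.44, others 23.26 to 24.4), replicate 2 for Sall4 (3.117, others 0.6419 to 1.027), and replicate 3 for Palmd (11.74, others 5.991 to 6.934), Dok5 (87.4, others 67.03 to 69.09) and Aqp4 (1.772, others 0.7705 to 0.8768). In WT TBR2+ cells they were replicate 3 for Prdm16 (67.57, others 39.2 to 42.72) and Cux2 (88.32, others 72.72 to 73.67), replicate 1 for Rassf10 (0.909, others 0.2749 to 0.3121) and replicate 4 for Fosl2 (20.07, others 9.219 to 10.61). The rest were KO TBR2+ replicate 1 for Kif26b (128.7, others 85.48 to 91.96), KO PAX6-TBR2- replicate 4 for Itga6 (79.75, others 61.08 to 61.44) and WT PAX6-TBR2- replicate 3 for Gabra2 (26.1, others 20.37 to 20.95). Such a gap was met in 13 of 248 groups (5.24%), and chance gives about 1 in 20.

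Drawn splits of the libraries did not exclude chance for the counts of interaction genes given next. By a test of the difference itself, genotype effects differed between populations. Between TBR2+ and PAX6+ this held for 89 genes, including Cyp26b1 (-4.72), Rassf10 (4.21), Col22a1 (4.18), Shisa9 (-3.57), Sema3c (2.90), Ndrg1 (2.81), Cckar (-2.79), Mme (2.75), Kcna2 (-2.60) and Gabra2 (-2.48). Between PAX6-TBR2- and PAX6+ it held for 117, including Npy (-5.88), Cyp26b1 (-4.24), Plcxd3 (-4.11), Kcna6 (-3.91), Gabra2 (-3.54), Ppp1r1b (3.37), Prokr2 (-3.32), Shisa9 (-3.00), Pdzrn3 (-2.38) and Grm5 (2.37). Between PAX6-TBR2- and TBR2+ the 7 genes were Fosl2 (-2.28), Pbx3 (2.19), Pdzrn3 (-2.06), Prokr2 (-2.06), Dscaml1 (1.86), Akap12 (1.26) and Slc17a6 (-0.89). Outside the counts used for the main results, the reads behind the deposited normalized values were 1.47 times the raw reads in WT TBR2+, 1.48 times in KO TBR2+, 1.7 times in WT PAX6-TBR2- and 1.44 times in KO PAX6-TBR2-.

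Many genes passed in PAX6+ (517) and TBR2+ (223) and 1 in PAX6-TBR2-, in fits that leave out a structure of the libraries, which shows in the 623 genes called between replicates 1 and 2 and replicates 3 and 4 of PAX6-TBR2-. The median effect of genes called in TBR2+ was 0.631 times as large in PAX6-TBR2- as in PAX6+ (95% interval 0.481 to 0.819; 195 genes), which by itself leaves open a wider spread or lower depth as the whole cause. The standard errors, from fits without the replicate block, argue against it for those fits. In PAX6-TBR2- those of genes called in TBR2+ were 1.06 times those in PAX6+ (0.994 to 1.13). Those of genes called in PAX6+ were 0.967 times those in TBR2+ (0.92 to 1, 420 genes). Against the population of the call itself, a comparison that the choice of genes biases upwards, they were 1.13 and 1.09 times as large. All intervals of this paragraph were drawn over genes, which share the same libraries, so they do not measure the spread between libraries. Cells outside the Emx1 lineage in the sort, such as the interneurons whose genes were high there and which the gate does not remove, could dilute every effect alike, and a correlation of 0.676 (0.584 to 0.762; 153 genes) between the effects in TBR2+ and PAX6-TBR2- of genes called in TBR2+ leaves this open. A smaller dependence of neurons on Prdm16 remains an untested biological explanation.

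Ribosomal protein genes had lower medians in KO in all 3 populations (-0.20, -0.23 and -0.38). After removal of a trend with gene length and GC content the medians were -0.20, -0.23 and -0.33. They were at least 0.874 times the earlier value (95% interval, drawn over genes, 0.574 to 1.09), which argues against that trend as the whole cause. With each library left out in turn the median nearest 0 was -0.1686, which argues against a single outlying library. A difference in RNA quality or amplification between KO and WT cells and a biological difference stay open, as untested.

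Pdzrn3 (101149609 to 101377897), which rose in PAX6+ and TBR2+, lies on chromosome 6, as does Emx1 (85187438 to 85204462), where the Cre allele was inserted. Nearer to Emx1 lie Cyp26b1 (84571414 to 84593908; log2 fold change 5.40 in PAX6+) and Tgfa (86195223 to 86275719; -2.10 in TBR2+). For Pdzrn3, a log2 fold change of 0.0102 in PAX6-TBR2- (-0.393 to 0.413 at 2 SE on either side) argues against a strain variant that changes read mapping, which would act in all 3 populations. DNA of another strain carried along with the Cre allele could raise the share of called genes nearby, and within 20 Mb of Emx1 7 of 186 genes were called in PAX6+ (odds ratio 1.04, 95% interval 0.409 to 2.2, exact p = 0.843) and 5 of 161 in TBR2+ (1.81, 0.574 to 4.38, exact p = 0.211), so this stays open. A dependence on Prdm16 in progenitors stays open as well. An effect of Cre or of the altered Emx1 allele was not tested and cannot be told apart from it. Emx1 had log2 fold changes of -0.36, -0.23 and -0.60 in PAX6+, TBR2+ and PAX6-TBR2-, none passing.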

How the results depend on the processing

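The fit to recovered reads and the thinning of WT PAX6-TBR2- replicate 4 were chosen after the data had been seen. The first called 232 genes in TBR2+ and 1 in PAX6-TBR2-, and the second 1. Of the counts and correlations, 49 values under other settings stayed within their limits and 29 moved. With 1 library left out 110 stayed and 22 moved. Of named genes and lists, 1609 values kept their direction and side of the threshold, 68 gained a call, 76 lost one and 1 reversed; with 1 library left out these numbers were 1891, 5, 195 and 13. In PAX6+ 517 genes became 1045 with the replicate block, 220 with a minimum log2 fold change of 1, and 1077 with the block and the length and GC trend removed. Among named genes and lists of PAX6+, the block changed no call other than those given with the results. In TBR2+ 223 became 728 without a filter, 356 with DESeq2, 720 with the replicate block, 88 with the minimum fold change and 885 with the block and trend removed; the trend alone moved 139 higher and 84 lower to 123 and 117. In PAX6-TBR2- 1 became 38 without a filter, 24 with DESeq2, 153 with the replicate block, 6 with all populations in 1 fit (0 of them the same gene), 4 with the trend removed and 180 with block and trend. Replicate numbers did not meet the pairing rule in TBR2+ (correlations 0.046 to 0.408; 6 of 8 libraries closest to their own number) or PAX6-TBR2- (0.082 to 0.365; 7 of 8), so the block is a hint from the data there. With an estimated correlation 0 lists were called in each population (9, 8 and 6 at the preset one), and with fry 5 (4 of the 9), 0 and 1. Without a filter the interactions gave 329, 219 and 126 genes for TBR2+ and PAX6+, PAX6-TBR2- and PAX6+, and PAX6-TBR2- and TBR2+; DESeq2 gave 163 for the first and 27 for the last, and the block 2 for the last, where Fosl2, Pbx3, Prokr2, Akap12 and Slc17a6 did not pass (adjusted p = 0.1633 to 0.2317) at differences of -2.294, 2.167, -2.102, 1.226 and -0.895. Correlations of fold changes over genes of at least 10 CPM were 0.419, 0.321 and 0.441. Without a filter Pdzrn3 in PAX6-TBR2- was at -0.005. The causes were not tested.

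With 1 library left out, called genes ranged from 358 to 529 in PAX6+, 121 to 420 in TBR2+ and 1 to 3 in PAX6-TBR2-, and lists from 7 (without WT replicate 1, among others) to 14 (without WT replicate 2), 5 to 9 and 3 to 8. Interactions ranged from 71 to 137, 84 to 109 and 3 to 10, WT contrasts from 8080 to 8487, 9192 to 9694 and 5711 to 6391, and correlations from 0.267 to 0.315, 0.181 to 0.23 and 0.252 to 0.35. Uncalled values near 0 changed sign: Pax6 ranged from -0.076 to 0.008 in PAX6+, -0.21 to 0.069 in TBR2+ and -0.355 to 0.038 in PAX6-TBR2-, Prdm16 in TBR2+ from -0.18 to 0.129 and Pdzrn3 in PAX6-TBR2- from -0.139 to 0.155. In the leave-out fits 32 of 48 named genes in PAX6+ and 24 of 34 in TBR2+ kept their call throughout. In simulated counts, which leave out any structure of the libraries, 38.8%, 47.8% and 47.8% of 1.5-fold changes were called in the 3 populations.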

Other observations

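The count of GABA-A receptor subunit genes was a test chosen after the values of Gabra2 and Gabrg1 were seen. Besides those genes, Gabrb1 rose in PAX6+ cells (log2 fold change 1.32, SE 0.15, adjusted p = 3.25e-05 in edgeR), and in TBR2+ cells Gabra2 (1.75, SE 0.17, adjusted p = 6.33e-05) and Gabrg1 (2.11, SE 0.37, adjusted p = 0.00736) rose. A candidate explanation, that subunit genes as a family change more often in KO PAX6+ cells, was tested without Gabra2 and Gabrg1: 1 of 8 other subunit genes was called (odds ratio 3.8, 95% interval 0.0842 to 29.7, Fisher exact p = 0.256, two-sided), which leaves it open.

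Of genes that overlap a named gene on the opposite strand, 6 of 9 passed in PAX6+ cells and 5 of 12 in TBR2+ cells in edgeR; the 4 in PAX6-TBR2- cells did not, though 4 had an unadjusted p under 0.05. Within Prdm16, Gm13134 (0.91, adjusted p = 0.002055), Gm13133 (0.86, 0.01563) and B230104I21Rik (0.86, 0.02651) rose in PAX6+ cells while Prdm16 was at -0.43. Mecomos rose by 5.60 on the log2 scale with Mecom (adjusted p = 0.0001979), and Gm26911 inside Pdzrn3 by 2.23 in PAX6+ and 1.81 in TBR2+. Gm26846 inside Ephb1 rose by 1.02 in PAX6+. These genes were chosen for their overlap with the spans of named genes. Without strand, and with exons not compared, their reads may be mixed with those of their hosts.

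Xist was at 19.7, 25.3 and 18.6 CPM in KO replicate 4 of PAX6+, TBR2+ and PAX6-TBR2-, and at 1261 to 5676 CPM in all other libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had counts in every library. In each population they were highest in KO replicate 4, with Ddx3y at 56, 40.3 and 19.6 CPM. The sex make-up of KO replicate 4 thus stood apart in every population, which goes with a shared origin of those libraries. What the other numbers mark stays open.

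The 8 libraries of a comparison can be split into 4 and 4 in 35 ways, the real one included. For genes, chance could be excluded in PAX6+, where 1 split, the real one, reached 517 and the highest other called 1; among the 8 splits that part all replicate pairs the highest other called 0. It could not in TBR2+, where 2 reached 223 and the highest other called 421, nor in PAX6-TBR2-, where 3 reached 1 and the highest other called 623. The split with 421 set KO replicate 1 and WT replicates 1 to 3 against the rest, and that with 623 set replicates 1 and 2 of both genotypes against 3 and 4; both point to a structure of the samples, and the blocked counts were 720 and 153. Pdzrn3 in TBR2+ was at 317.3 CPM in KO replicate 1 and 94.02 CPM in WT replicate 4, each on the side of its own genotype. For lists, chance could not be excluded: 5 splits reached 9 in PAX6+ (highest other 11), 11 reached 8 in TBR2+ (11) and 17 reached 6 in PAX6-TBR2- (12).

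Of 100 drawn splits for the interactions, 4 reached 117 genes between PAX6-TBR2- and PAX6+ (highest other 940). This is under the limit of 0.05 set beforehand, but only narrowly. The splits are a draw from many and do not keep the replicate numbers together, so chance is not taken as excluded. Of the same number, 5 reached 89 between TBR2+ and PAX6+ (172) and 6 reached 7 between PAX6-TBR2- and TBR2+ (306), where chance could not be excluded. Which splits gave 940 and 306 genes was not kept. Draws could also swap the genotype sides in 1 population, so these counts need not come from a structure of the samples. For the correlation of fold changes, 1 of 35 joint splits, the real one, reached 0.366 between PAX6-TBR2- and TBR2+ (highest other 0.286). These splits regroup same-numbered libraries together. Between those populations the deviations of same-numbered libraries correlated at -0.182 to -0.039 in WT and -0.19 to 0.109 in KO. The numbers thus need not match there, and chance is not taken as excluded. It could not be excluded between TBR2+ and PAX6+ (2 of 35, 0.322, highest other 0.323) or PAX6-TBR2- and PAX6+ (5 of 35, 0.241, highest other 0.284). In each of the 3 contrasts of WT populations 1 of 35 splits, the real one, reached the count (8570, 9530 and 6309 genes, highest other 0), so that chance could be excluded.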
